A study of Mus musculus with 6 samples.

How the data were processed

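RAW264.7 is a mouse macrophage-like line derived from a leukaemia, widely used as a model of inflammatory macrophages. Per the labels, the cells were transfected with a mimic of the microRNA miR-125b or with a negative control, and mRNA was sequenced from 3 samples of each kind with a SMARTer library kit from total RNA. Group and number were taken from the sample titles. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The labels do not say which arm of miR-125b the mimic holds, and the microRNA itself was not measured by these libraries.

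The deposited table gives one FPKM value (fragments per kilobase of gene, scaled to mapped depth) for each of 16665 Ensembl gene identifiers in each of the 6 samples. Per the submitters' processing notes, fastp, HISAT2, DESeq2 and the mouse build mm10 were used. Versions, the annotation, the counting tool and the strand setting are not given in the sources used here. In the table each gene was above 0 in at least 2 samples, no columns were duplicated, and the rule behind any filter is not given in the sources used here. Gene symbols, positions, exon lengths and 3′ untranslated regions (3′ UTRs) came from GENCODE release M21 on GRCm38, the assembly that mm10 names. Of the identifiers, 16582 were found there and 83 were not.

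FPKM values are not counts, so no count test was the main test. The depth of each library was recovered from the low values, because the FPKM of a gene with few fragments moves in whole steps that depend on its exon length. Between 98.5% and 99.0% of low values, up to 20 fragments, came out whole within 0.1 fragment. The recovered depths were 15.60, 16.81 and 14.71 M fragments in negative controls 1, 2 and 3, and 14.45, 16.60 and 15.39 M in mimics 1, 2 and 3. Depth alone therefore differed little between groups. How many fragments came from one original molecule was estimated from genes expected at 3 to 20 fragments: the share of them at 0 gives the number of molecules, under Poisson sampling, and fragments were divided by it. Pairs of libraries were compared over genes with a chi-square statistic on recovered fragments. The lowest values were 4.49 per gene between negative controls 1 and 2 and 6.37 between mimics 1 and 2. Sampling noise gives about 1 if each fragment is a molecule and more where fragments share one (2.19 to 2.90 per molecule in these 4 libraries), so these values do not settle whether the samples are separate. All 6 were kept as labelled.

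Genes with a mean FPKM of at least 1 over the 6 samples (10166) were tested with limma 3.58.1 in R 4.3.3, on log2(FPKM + 1), with a mean-variance trend, a two-sided test, Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change is mimic minus negative control on that scale, which understates changes of low genes. SE is the standard error of limma's moderated fit, and SD is that of the FPKM values of 3 libraries.

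Before the data were examined, 33 gene lists, the named genes and the alternatives were fixed. The 26 lists with at least 5 tested members were tested with limma's camera, which asks whether a list's genes shift relative to all other genes, with a preset correlation of 0.01 between genes. The adjustment was over the 26 lists. Each list was tested again with camera and a correlation estimated from the residuals, and with fry, which asks whether a list's genes move one way on balance or, in its mixed form, change in either direction. Genes in a list were also adjusted over the list alone. The genes named are the 6 with the smallest p in each direction, since too few passed for a ranking by fold; up to 4 members with the smallest p from each list; all tested members of the pyroptosis list; and Actb and Gapdh as checks. Predicted genes without a name were passed over in the first group.

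The seed of miR-125b-5p is bases 2 to 8 of UCCCUGAGACCCUAACUUGUGA. Its sites CTCAGGGA (8mer), CTCAGGG (7mer-m8) and TCAGGGA (7mer-A1) were searched in the longest annotated 3′ UTR of each gene, taken from the coding end in the annotation to the transcript end. Genes with a site were set against genes with a 3′ UTR and none, with camera and with the difference of medians, whose 95% interval came from 2000 bootstrap draws over genes. Genes are not independent replicates, so that interval covers the spread of genes and not that between libraries. All 7mers found in at least 100 genes' 3′ UTRs were ranked by the mean fold change of the genes holding them, as planned, and also by its difference from other genes over the standard error, a departure from the plan. Sites of both passenger strands were tested likewise.

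Alternatives fixed in advance covered the pseudocount, the filter, scaling, library weights, a replicate block, each library left out, and for lists and sites the correlation and the 3′ UTR used. After the data were seen, several were added: removal of a length and GC trend from each library (a loess surface, span 0.3, of each gene's deviation from its mean on transcript GC and exon length); leaving out replicate 3 of both groups; both together; leaving out negative control 3 with the trend removed; and limma voom on recovered fragments. Deviations from the group means correlated between same-numbered samples at 0.287, 0.183 and 0.339, each above the limit of 0.1 set for treating the numbers as pairs. Nothing in the labels says what a number stands for, and negative control 2 correlated better with mimic 1 (0.308) than with mimic 2.

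The fit was tested on simulated data with 200 changed genes among 10166, drawn from the real means and spread, the changed ones among genes with a mean log2 value above 3. With the spread of all 6 libraries it recovered 30%, 64%, 86% and 94% of genes changed 1.5-, 2-, 3- and 4-fold, and called 5 unchanged genes. With the spread seen without negative control 3, still drawn for 6 libraries, it recovered 68%, 84%, 96% and 96%, and called 7 unchanged genes. Noise was drawn independently for each gene and alike for all 6 libraries, whereas in the real data negative control 3 stood apart. The shares therefore do not give the power of the fits to the real libraries.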

Results

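Gene expression was measured in RAW264.7 macrophage-like cells transfected with a miR-125b mimic (3 libraries) or with a negative control (3 libraries). The title of the series names atherosclerosis and pyroptosis, the lytic form of cell death run by inflammasomes and gasdermins. The comparison asks how raised miR-125b changes the transcriptome, and the genes of that pathway in particular. Depth lay between 14.45 M and 16.81 M fragments, and between 13266 and 15470 genes were above 0 per library.

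No single gene passed. Of 26 gene lists, 15 passed camera at its preset correlation, 3 higher and 12 lower. With an estimated correlation camera passed 0 lists (smallest adjusted p = 0.190). Fry, which asks a different question, passed 0 (smallest adjusted p = 0.0568), as did its mixed form. For the heat shock and microRNA pathway lists the estimated correlation (−0.024 and −0.0048) was below the preset one. Their camera adjusted p still went from 0.00135 to 0.190 with it. In these lists the loss of the call therefore cannot be put down to correlation between genes. The setting thus changes more than the correlation. In the other lists too, its p cannot be read as an effect of correlation alone. At the preset correlation, cytosolic ribosomal proteins (median log2 fold change −0.25 over 53 genes), nuclear-encoded respiratory chain subunits (−0.21 over 38), chaperones of the heat shock response (−0.31 over 14) and antigen presentation genes (−0.23 over 17) fell. Genes of the microRNA pathway (0.23 over 22), those encoded by mitochondrial DNA (0.37 over 13) and mitotic genes (0.13 over 38) rose. With the trend of fold changes on transcript length and GC removed, the 3 higher calls were lost (medians 0.071, 0.20 and 0.057; adjusted p = 0.137, adjusted p = 0.290 and adjusted p = 0.136), as was antigen presentation (adjusted p = 0.136).

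By limma 0 of 10166 genes passed an adjusted p of 0.05, the smallest being 0.289, and limma voom on recovered fragments also called 0. At an unadjusted p under 0.05 there were 1344 genes (809 higher, 535 lower), where 508 would be reached by chance, and 1393 by voom. Of the 9 other groupings of 3 against 3, those with negative controls 1 and 2 on one side gave similar numbers (1971 genes when put with mimic 1, 1379 with mimic 2 and 1171 with mimic 3), and the other 6 gave 39 to 430. An excess over 508 was thus also seen in groupings other than the real one. Those groupings still set negative controls 1 and 2 against 2 of the mimics and so carry part of the real contrast. They cannot tell whether the excess depends on the mimic. In 2046 genes (20.1%; chance gives 10%) the 3 values of one group all lay above those of the other, 1285 of them higher and 761 lower in the mimic libraries. Without negative control 3, 2412 genes passed, 1175 higher and 1237 lower. In 2003 of these (83.0%; 65.7% of all tested genes) the library left out lay nearer to the mean of the mimics than to that of the other controls. It did not bear these calls out.

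The genes with the smallest p did not pass either (limma, each adjusted p = 0.332). Highest among them were Gapdhs, the testis form of a glycolytic enzyme, at 1.69 ± 0.268 FPKM in controls and 3.82 ± 0.344 with the mimic (SD, n = 3; log2 fold change 0.84, SE 0.14). Nktr, a cyclophilin-related protein of natural killer cells, had a log2 fold change of 0.76 (SE 0.13) and Zfp280c 0.74 (SE 0.13). The lipid transfer protein Vps13c stood at 0.58 (SE 0.10), the nuclear receptor corepressor Lcor 0.61 (SE 0.12) and the giant scaffold protein Ahnak 0.61 (SE 0.12). On the lower side stood the mitochondrial nucleotide kinase Nme4 at −0.95 (SE 0.17), from 3.26 ± 0.510 to 1.20 ± 0.329 FPKM. Next to it were Ndufb6, a complex I subunit, at −0.86 (SE 0.16), Mcrip1 at −0.82 (SE 0.14), the membrane protein Igsf8 at −0.69 (SE 0.12), Smdt1, part of the mitochondrial calcium uniporter, at −0.68 (SE 0.12) and Prkcsh, the glucosidase II beta subunit, at −0.63 (SE 0.11). With the length and GC trend removed the higher ones other than Gapdhs (1.08) were over 1.5 times smaller (Nktr 0.34, Zfp280c 0.48, Vps13c 0.33, Lcor 0.37 and Ahnak 0.36). So was Mcrip1 on the lower side (−0.53). The lower ones stood between −0.48 (Smdt1) and −0.79 (Ndufb6). In all 12 the 3 mimic values as deposited lay on one side of the 3 control values. The housekeeping genes used as checks were not level: Actb read 237 ± 38.0 and 187 ± 30.6 FPKM (log2 fold change −0.35, SE 0.18) and Gapdh, which has many processed pseudogenes and is uncertain, 45.7 ± 2.61 and 30.7 ± 10.4 (−0.61, SE 0.23).

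Pyroptosis genes gave no call with all 6 libraries in the main limma fit or in voom. Of the 17 tested members of the pyroptosis and inflammasome list, 0 passed over all genes and 0 adjusted over the list alone by limma, while 2 were higher and 1 lower at an unadjusted p under 0.05; voom called 0 over all genes. The gasdermins Gsdmd and Gsdme pointed in opposite directions as deposited. Their contrast shrank with the length and GC trend removed (−0.11 and 0.035). Without negative control 3 as well it was gone (0.011 and −0.0082, limma adjusted p = 0.967 and 0.969). Gsdmd (ENSMUSG00000022575; GRCm38 chromosome 15, 75862327 to 75867408), the pore former cleaved by inflammatory caspases, read 26.7 ± 0.524 FPKM in controls and 21.8 ± 2.16 with the mimic (log2 fold change −0.29, SE 0.11, limma adjusted p = 0.357). Gsdme (ENSMUSG00000029821; chromosome 6, 50188888 to 50263862), cleaved by caspase-3, read 3.31 ± 0.620 and 4.53 ± 0.0357 (0.37, SE 0.14, limma adjusted p = 0.355). Nek7, the NLRP3 licensing kinase, read 17.8 ± 2.44 and 22.4 ± 2.12 FPKM (0.32, SE 0.14). Without negative control 3, 4 of the 17 passed: Ninj1 (−0.72, adjusted p = 0.00499), Aim2 (0.38, adjusted p = 0.0223), Gsdme (0.48, adjusted p = 0.0234) and Nek7 (0.42, adjusted p = 0.0297), and Gsdmd did not (−0.30, adjusted p = 0.0691). With the length and GC trend also removed none of the 4 did (−0.26, 0.21, −0.0082 and 0.064, with limma adjusted p = 0.0722, 0.106, 0.969 and 0.662). Negative control 3 itself read 78.6, 53.7, 3.98 and 20.5 FPKM for these 4, against mimic means of 81.0, 54.4, 4.53 and 22.4. It lay nearer to those than to the other controls, so the 4 calls rest on leaving it out.

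The sensors and other effectors gave no call with all 6 libraries in the main limma fit or in voom either. Nlrp3, the best known inflammasome sensor, read 2.12 ± 1.42 FPKM in controls and 2.72 ± 1.18 with the mimic (log2 fold change 0.33, SE 0.43), and its estimate turned to −0.14 without negative control 3 (adjusted p = 0.744). Casp1, the inflammasome protease, read 6.66 ± 0.396 and 7.30 ± 1.78, Casp4 2.94 ± 0.422 and 3.24 ± 0.0464, and Casp8 11.5 ± 1.48 and 13.3 ± 2.97. The DNA sensor Aim2 had a log2 fold change of 0.26 (SE 0.14), and Ninj1, which ruptures the membrane at the end of lysis, −0.46 (SE 0.21), from 115 ± 31.7 to 81.0 ± 3.09 FPKM. Il18, a cytokine released through gasdermin pores, read 18.9 ± 1.17 and 18.0 ± 2.79. Txnip (0.21, SE 0.37; −0.26 without negative control 3, adjusted p = 0.111), P2rx7 (0.16, SE 0.20), Hmgb1 (0.03, SE 0.17), Nlrp1b (0.13, SE 0.19), Naip2 (0.25, SE 0.18), Naip5 (−0.03, SE 0.14) and Naip6 (0.13, SE 0.14) completed the tested members. Without negative control 3, P2rx7 stood at −0.018, Nlrp1b at −0.020, Naip5 at 0.039 and Hmgb1 at 0.20, none of them passing limma. Naip2, Naip5 and Naip6 are near-identical copies and are uncertain. Under the filter lay Pycard, the inflammasome adaptor that RAW264.7 cells are known to lack, at 0.0261 and 0.0121 FPKM, and Il1b at 0.139 and 0.0816. Il1a, Gbp2, Nlrc4, Irgm1 and Nlrp1a also lay there. As a list, 13 members were higher and 4 lower, with a median log2 fold change of 0.13 (camera adjusted p = 0.368; adjusted p = 0.783 with an estimated correlation). The median was 0.071 without negative control 3, 0.24 without mimic 3, 0.035 with the length and GC trend removed and −0.018 with that trend and negative control 3 both left out.

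**Figure D1:**
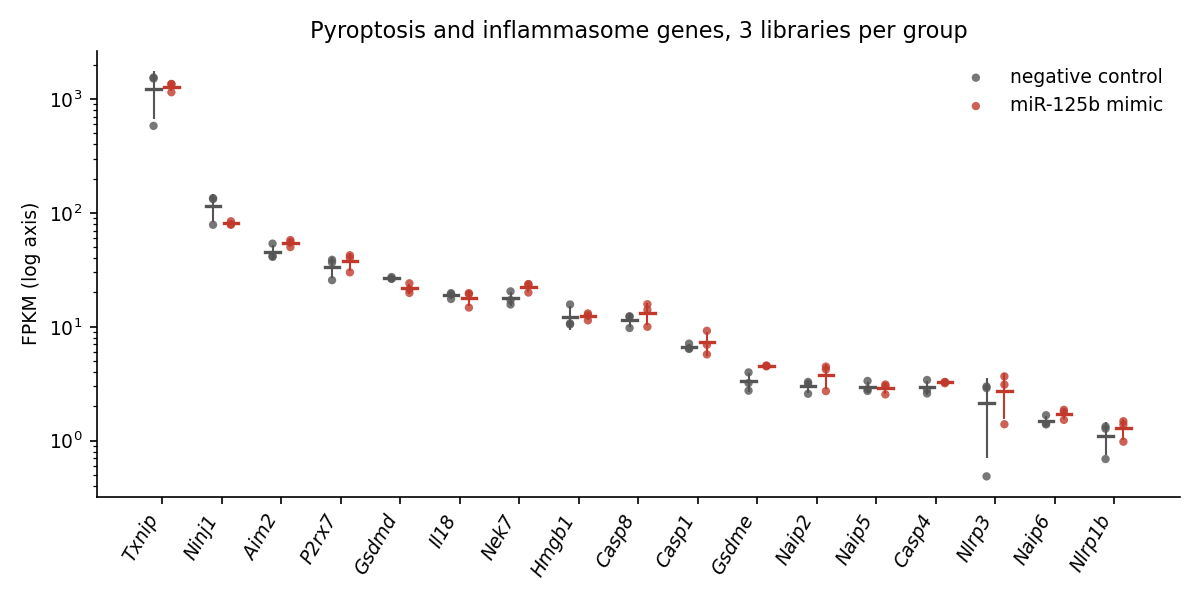
FPKM (log axis) of the 17 tested pyroptosis and inflammasome genes; points are single libraries, grey for negative control and red for mimic, horizontal bars are means and vertical bars ± 1 SD of 3 libraries. Gsdmd read 26.7 FPKM in controls and 21.8 with the mimic and Gsdme 3.31 and 4.53, and none of the 17 passed the main limma fit.

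Genes reported elsewhere as miR-125b targets were scattered around 0. Of 26 tested, 10 were higher and 16 lower, with a median log2 fold change of −0.078 (−0.17 to 0.00048 with 1 library left out; camera adjusted p = 0.284; adjusted p = 0.815 with an estimated correlation). By limma 0 passed over all genes and 0 adjusted over the list alone, 1 was higher and 1 lower at an unadjusted p under 0.05, and voom called 0 over all genes. The lower one was Bak1 (ENSMUSG00000057789), a pro-apoptotic BCL2 family member, at 19.2 ± 5.26 FPKM in controls and 12.6 ± 1.35 with the mimic (−0.54, SE 0.21, adjusted p = 0.351). Its 3′ UTR holds an 8mer site, CTCAGGGA, on the minus strand of GRCm38 chromosome 17, bases 27020316 to 27020323, starting at base 608 of the 1121 bases of the 3′ UTR, in the context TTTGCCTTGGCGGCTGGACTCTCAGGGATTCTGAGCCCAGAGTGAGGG. Dicer1, the microRNA processing enzyme, was the higher one at 0.33 (SE 0.12), and the p53-induced killer Bbc3 (−0.33, SE 0.20) and the phosphatase subunit Ppp1r12a (0.30, SE 0.18) followed. A seed site was present in 24 of the 26, of which 9 were higher and 15 lower (median −0.078). Without negative control 3 the list fell (median −0.17, camera adjusted p = 0.0146; adjusted p = 0.304 with an estimated correlation) and Bak1 passed (−0.77, limma adjusted p = 0.00758). With the length and GC trend also removed neither the list nor Bak1 passed (Bak1 −0.41, limma adjusted p = 0.0641). For Bak1 negative control 3 read 13.4 FPKM, within the 11.5 to 14.1 of the mimics, against 23.6 and 20.8 in the other controls. On the values as deposited, the list also fell with array weights (−0.12, camera adjusted p = 0.0330). It did so too without replicate 3 of both groups (−0.18, camera adjusted p = 0.0209).

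Across all genes with a 3′ UTR, those holding a miR-125b-5p seed site were not lower than those without. Genes with an 8mer site (496) had a median log2 fold change of 0.070 and the 7242 genes without any site 0.021, a difference of 0.049 (95% interval 0.023 to 0.069 over genes; camera adjusted p = 0.207 over 4 site classes). The difference was 0.020 for 7mer-m8 sites (919 genes, adjusted p = 0.322) and 0.085 for 7mer-A1 sites (649 genes), which were higher (adjusted p = 0.0126; the p with an estimated correlation was 0.296, unadjusted). For any site (2064 genes) it was 0.049 (adjusted p = 0.142). Their 3′ UTRs were longer, with a median of 2205 bases against 914, and 3′ UTR length itself went with the fold change (Spearman's rho 0.425 across genes, which are not independent replicates). With the length and GC trend removed the 8mer difference was 0.013 (95% interval −0.0055 to 0.035) and that of 7mer-A1 sites 0.029 (adjusted p = 0.743). Among 15189 7mers ordered from the lowest mean fold change of the genes holding them, CTCAGGG ranked 950, and 11426 once 3′ UTR length and GC were regressed out. By the mean difference over its standard error, a measure not in the plan, the ranks were 2687 and 12580. A fall of 0.1 added to the 8mer genes gave an unadjusted camera p of 0.0143 as deposited (0.437 with an estimated correlation), so a fall of that size was not reliably detected there. With the trend removed it gave a camera p of 6.57e-06 (0.00115 with an estimated correlation).

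Sites for the passenger strands gave no fall either. Genes with TAACCCG (miR-125b-1-3p, 110 genes) differed by 0.087 and those with TGACTTG (miR-125b-2-3p, 1329 genes) by 0.12, both higher (camera adjusted p = 0.0185 and adjusted p = 4.56e-06). With the trend removed the differences were 0.010 and 0.026 (adjusted p = 0.899 and adjusted p = 0.344).

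**Figure D2:**
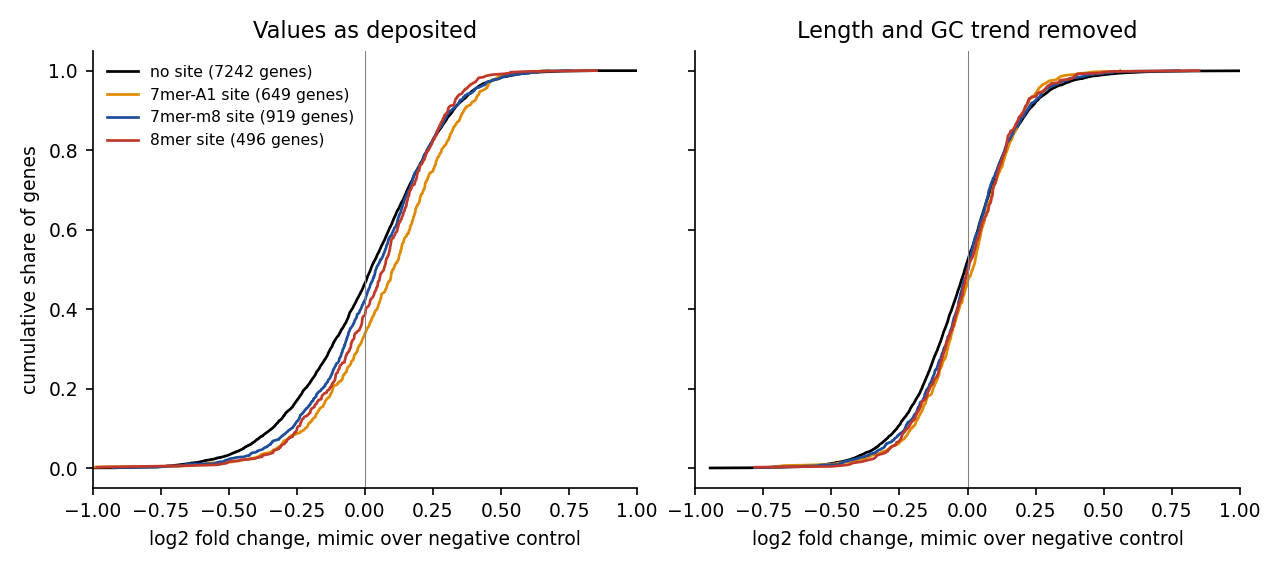
Cumulative share of genes (vertical axis) by log2 fold change, mimic over negative control (horizontal axis), for genes with an 8mer (496), 7mer-m8 (919), 7mer-A1 (649) or no site (7242) for miR-125b-5p; left, values as deposited, right, with the length and GC trend removed. On the right the 8mer and no-site curves lie 0.013 apart at the median, and on neither side does the 8mer curve lie to the left at its median.

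Genes of translation and respiration had the smallest p by camera at its preset correlation on the values as deposited. Of 53 ribosomal protein genes 50 were lower and 3 higher (camera adjusted p = 8.77e-11; adjusted p = 0.190 with an estimated correlation). Rpl8 read 897 ± 85.1 FPKM in controls and 576 ± 73.2 with the mimic (log2 fold change −0.64, SE 0.14), Rps3 364 ± 24.4 and 272 ± 11.7 (−0.42, SE 0.11), Rps18 −0.45 (SE 0.13) and Rpl18 −0.40 (SE 0.12). Ribosomal protein genes have many processed pseudogenes, so single values are uncertain. Of 38 subunits of oxidative phosphorylation, 34 were lower and 4 higher (adjusted p = 2.96e-07; adjusted p = 0.449 with an estimated correlation). They included Ndufa2 of complex I at −0.59 (SE 0.13), Uqcrq of complex III at −0.63 (SE 0.21), Cox4i1 of complex IV at −0.51 (SE 0.14) and Ndufs3 at −0.31 (SE 0.12). Both lists fell also with the length and GC trend removed, to medians of −0.14 and −0.15 (adjusted p = 0.000334 and adjusted p = 0.00185), but not with an estimated correlation as well (adjusted p = 0.592 and adjusted p = 0.471). Under quantile normalisation the ribosomal protein median was −0.083 (adjusted p = 0.0906) and its call was lost.

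Transcripts of the mitochondrial genome went the other way. Of 13, 11 were higher and 2 lower (median 0.37, and 0.58 without mimic 3; camera adjusted p = 0.0254; adjusted p = 0.604 with an estimated correlation). The complex I subunits mt-Nd5 (1038 ± 128 and 1608 ± 14.2 FPKM; log2 fold change 0.64, SE 0.14) and mt-Nd6 (0.57, SE 0.14) passed adjusted over the list alone (limma adjusted p = 0.0260 and adjusted p = 0.0304) and not over all genes. With the length and GC trend removed mt-Nd5 stood at 0.40 and mt-Nd6 at 0.26 (limma, unadjusted p = 0.0272 and 0.251). The gene mt-Nd6 lies on the opposite strand, and with the strand setting unknown its value is uncertain. For mt-Nd2 (0.75, SE 0.35) and mt-Nd3 (0.98, SE 0.55) the errors were wide. The list call was lost without negative control 1, negative control 2, mimic 1 or mimic 2 (medians 0.29, 0.23, 0.28 and 0.25; adjusted p = 0.195, adjusted p = 0.145, adjusted p = 0.0592 and adjusted p = 0.0646), and with the length and GC trend removed (0.20, adjusted p = 0.290; these transcripts have a median GC of 37.1%). Ribosome biogenesis and MYC target genes did not pass (median −0.068, −0.32 to 0.069 with 1 library left out, 11 of 30 higher, camera adjusted p = 0.202). The nucleolar GTPase Gnl3 stood at 0.32 (SE 0.10), Utp20 at 0.24 (SE 0.12), the rRNA methyltransferase fibrillarin (Fbl) at −0.45 (SE 0.19) and Nme1 at −0.30 (SE 0.14). Without negative control 3 this list fell (−0.32, adjusted p = 0.00408; adjusted p = 0.403 with an estimated correlation).

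**Figure D3:**
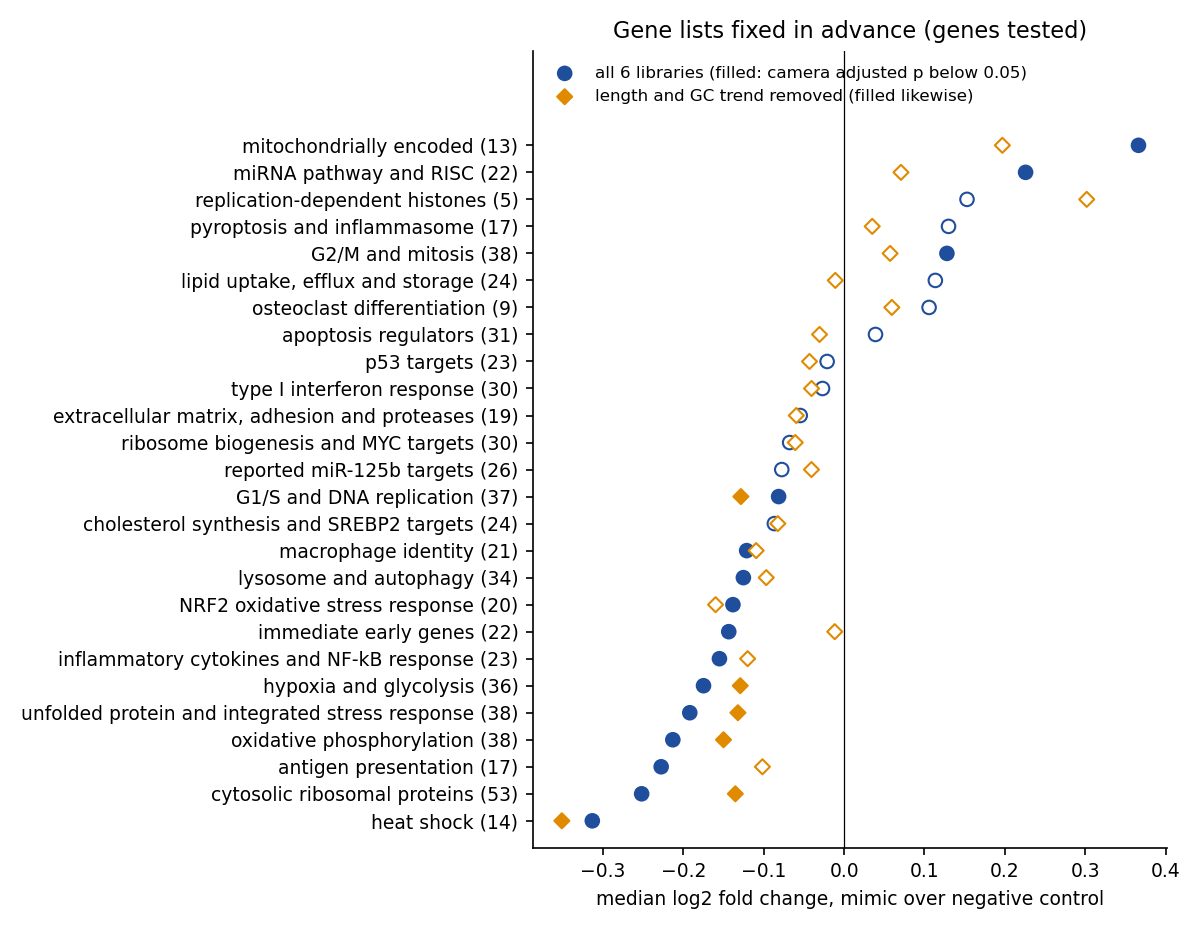
Median log2 fold change (horizontal axis) of the 26 tested gene lists with the number of genes tested; circles are values as deposited, diamonds values with the length and GC trend removed, and filled symbols passed camera at its preset correlation. As deposited 15 lists passed, with the trend removed 6, all of them lower, and with an estimated correlation 0.

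Stress response genes were lower. In the heat shock list 13 of 14 chaperone genes were lower (camera adjusted p = 0.00135; adjusted p = 0.190 with an estimated correlation). Among its members the HSP40 Dnajb1 stood at a log2 fold change of −0.51 (SE 0.12), the mitochondrial chaperonin Hspd1 at 161 ± 17.9 FPKM in controls and 126 ± 13.1 with the mimic (−0.34, SE 0.13), Hsp90ab1 at −0.33 (SE 0.15) and the co-chaperone Stip1 at −0.55 (SE 0.30). This list was as low with the length and GC trend removed (median −0.35, adjusted p = 0.000772; adjusted p = 0.471 with an estimated correlation). In the unfolded protein and integrated stress response 28 of 38 were lower (median −0.19, −0.33 to −0.12 with 1 library left out, adjusted p = 0.00296; adjusted p = 0.604 with an estimated correlation). Ddit4, an mTOR inhibitor, read −0.56 (SE 0.16), the chaperone cofactors Sdf2l1 −0.55 (SE 0.17) and Creld2 −0.38 (SE 0.13), while Dnajc3, an inhibitor of the kinase PERK, read 0.30 (SE 0.11). Hypoxia and glycolysis genes were lower in 25 of 36 (median −0.18, −0.27 to −0.13 with 1 library left out, adjusted p = 0.00188; adjusted p = 0.604 with an estimated correlation). Triosephosphate isomerase (Tpi1) stood at −0.42 (SE 0.20), the oxygen sensor Egln3 at −0.43 (SE 0.18) and adrenomedullin (Adm) at −0.48 (SE 0.23). Both of these calls held with the trend removed (−0.13 each, adjusted p = 0.0176 and adjusted p = 0.00997; adjusted p = 0.592 for both with an estimated correlation) and did not pass under quantile normalisation, where the first median stayed at −0.18 (adjusted p = 0.101) and the second was −0.064 (adjusted p = 0.354).

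The NRF2 oxidative stress response fell as a list, with 14 of 20 estimates negative and 2 genes lower at an unadjusted p under 0.05 (median −0.14, −0.22 to −0.14 with 1 library left out, camera adjusted p = 0.0218; adjusted p = 0.604 with an estimated correlation). Haem oxygenase Hmox1, at 249 ± 7.63 FPKM in controls and 160 ± 36.0 with the mimic (log2 fold change −0.66, SE 0.16), and ferritin light chain Ftl1, at 1810 ± 300 and 1104 ± 146 (−0.71, SE 0.18), passed adjusted over the list alone (limma adjusted p = 0.0460 for both) and not over all genes. Ferritin heavy chain Fth1 (−0.33, SE 0.16) and transaldolase Taldo1 (−0.25, SE 0.11) were the next. Ferritin genes have many pseudogenes and are uncertain. The list did not pass with the length and GC trend removed (−0.16, adjusted p = 0.0864) or under quantile normalisation (−0.16, adjusted p = 0.190), though its median was no smaller.

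Macrophage identity genes fell as a list, 18 of 21 being lower (median −0.12, and −0.25 with adjusted p = 0.00408 without negative control 3; camera adjusted p = 0.00538; adjusted p = 0.604 with an estimated correlation). The signalling adaptors Tyrobp (223 ± 25.3 and 171 ± 2.09 FPKM; log2 fold change −0.38, SE 0.12) and Fcer1g (−0.28, SE 0.12) were lower, and the sialic acid receptor Cd33 higher (0.51, SE 0.17), none past the gene threshold. Antigen presentation genes were lower in 15 of 17 (median −0.23, adjusted p = 0.00135; adjusted p = 0.190 with an estimated correlation). The immunoproteasome subunit Psmb8 stood at −0.37 (SE 0.11) and the class I genes H2-Q7 at −0.40 (SE 0.14), H2-K1 at −0.31 (SE 0.15) and H2-D1 at −0.35 (SE 0.17), which share near-identical sequence and are uncertain. Lysosome and autophagy genes were lower in 21 of 34 (median −0.13, adjusted p = 0.0254; adjusted p = 0.616 with an estimated correlation and adjusted p = 0.0512 with the replicate number as a block). Among them were the cathepsins Ctsl (−0.45, SE 0.12), Ctsd (−0.33, SE 0.13) and Ctsb (−0.29, SE 0.13) and the sialidase Neu1 (−0.34, SE 0.17). With the length and GC trend removed the 3 calls were lost (medians −0.11, −0.10 and −0.097; adjusted p = 0.193, adjusted p = 0.136 and adjusted p = 0.0997). The lysosome call was also lost without negative control 1, mimic 1 or mimic 2 (medians −0.048, −0.11 and −0.11; adjusted p = 0.0960, adjusted p = 0.101 and adjusted p = 0.144), with a mean FPKM of at least 5 (adjusted p = 0.0520) and under quantile normalisation (−0.044, adjusted p = 0.406), which also ended the macrophage identity call (−0.056, adjusted p = 0.581).

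Inflammatory cytokine and NF-kB genes were lower in 17 of 23 (median −0.16, and −0.27 without negative control 3; camera adjusted p = 0.0368; adjusted p = 0.631 with an estimated correlation and adjusted p = 0.0512 with the block). Inducible nitric oxide synthase Nos2 read 26.5 ± 4.05 FPKM in controls and 19.1 ± 3.95 with the mimic (log2 fold change −0.46, SE 0.18), the chemokine Ccl5 −0.31 (SE 0.15), Icam1 −0.29 (SE 0.16) and Ier3 −0.40 (SE 0.19). Immediate early genes were lower in 14 of 22 (median −0.14, and −0.24 without negative control 3; adjusted p = 0.0231; adjusted p = 0.631 with an estimated correlation). The AP-1 subunit Jund stood at −0.54 (SE 0.20) and Jun at −0.49 (SE 0.19), and Maff at −0.35 (SE 0.14). Leaving out negative control 1, negative control 2 or mimic 2 ended both calls (for cytokines medians of −0.032, −0.024 and −0.14, adjusted p = 0.185, 0.183 and 0.0902, and for early genes −0.029, −0.079 and −0.075, adjusted p = 0.158, 0.0809 and 0.0902), as did mimic 1 for cytokines (−0.15, adjusted p = 0.0634). Both also ended on removal of the length and GC trend (−0.12, adjusted p = 0.136 and −0.012, adjusted p = 0.636, where camera pointed higher). The cytokine call was also lost with no filter (median −0.030, adjusted p = 0.0904), with a mean FPKM of at least 5 (−0.19, adjusted p = 0.0520) and under quantile normalisation (−0.067, adjusted p = 0.194), and that of early genes under quantile normalisation (−0.17, adjusted p = 0.0761). Early genes had a median GC of 54.5%.

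Type I interferon response genes did not pass (median −0.027, 14 of 30 higher, camera adjusted p = 0.364; adjusted p = 0.850 with an estimated correlation). Irf7, the transcription factor that amplifies interferon, read 12.5 ± 4.79 FPKM in controls and 6.48 ± 0.0634 with the mimic (log2 fold change −0.78, SE 0.27) and Ifi35 −0.54 (SE 0.21), while Ifi203 (0.35, SE 0.13) and the RNA sensor Eif2ak2 (0.36, SE 0.14) were higher. Without negative control 3 the list fell (−0.13, camera adjusted p = 0.0420, or 0.647 with an estimated correlation), and without mimic 3 the median was 0.090. For Irf7 negative control 3 read 6.99 FPKM, against 15.4 and 15.2 in the other controls and 6.44 to 6.56 in the mimics.

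Lipid handling genes, those nearest to foam cell formation in atherosclerosis, did not pass. For uptake, efflux and storage the median was 0.11 (13 of 24 higher; −0.080 without negative control 3 and −0.011 with the length and GC trend removed), the mean 0.0014 and camera pointed lower (adjusted p = 0.734; adjusted p = 0.856 with an estimated correlation). The scavenger receptor Cd36 read 2.12 ± 0.0583 FPKM in controls and 1.20 ± 0.371 with the mimic (log2 fold change −0.51, SE 0.17), the endosomal cholesterol exporters Npc1 0.40 (SE 0.14) and Npc2 −0.32 (SE 0.16), and the scavenger receptor Msr1 0.27 (SE 0.14). Cholesterol synthesis and SREBP2 targets had a median of −0.087 (−0.21 to 0.024 with 1 library left out; 8 of 24 higher, adjusted p = 0.364). Hsd17b7 stood at 0.35 (SE 0.18), Sc5d at 0.21 (SE 0.14), Fdft1 at −0.14 (SE 0.10) and Insig1 at 0.13 (SE 0.10).

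Adhesion and matrix genes did not pass as a list (median −0.055, −0.17 to −0.019 with 1 library left out, 6 of 19 higher, camera adjusted p = 0.129), although leaving out mimic 3 gave a call (−0.15, adjusted p = 0.0160; adjusted p = 0.407 with an estimated correlation). Itga4, the alpha chain of the VLA-4 integrin, was the 1 member past the threshold adjusted over the list alone (101 ± 3.49 and 158 ± 23.5 FPKM; log2 fold change 0.63, SE 0.14, limma adjusted p = 0.0393). It did not pass over all genes, and with the length and GC trend removed it stood at 0.32 (limma, unadjusted p = 0.0423). Osteopontin (Spp1) read 4891 ± 707 and 3571 ± 420 FPKM (−0.45, SE 0.18), the urokinase receptor Plaur −0.57 (SE 0.18) and the LFA-1 alpha chain Itgal −0.44 (SE 0.17). Osteoclast genes, relevant because RAW264.7 cells can form osteoclasts, had a median of 0.11 over 9 (0.057 without negative control 3; 7 higher, adjusted p = 0.767). Tnfrsf11a, the RANK receptor, read 10.6 ± 0.266 and 14.2 ± 0.400 FPKM (0.40, SE 0.10). It was the 1 member past the threshold adjusted over the list alone (limma adjusted p = 0.0477), not over all genes. Acp5 read −0.50 (SE 0.24), Car2 −0.18 (SE 0.11) and Clcn7 0.11 (SE 0.11).

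The microRNA pathway rose as a list, with 20 of 22 estimates positive and 5 genes higher at an unadjusted p under 0.05 (median 0.23, camera adjusted p = 0.00135; adjusted p = 0.190 with an estimated correlation). Ago2, the slicing Argonaute, read 58.7 FPKM in controls and 79.8 with the mimic (n = 3; log2 fold change 0.44, SE 0.11), Ago3 7.25 ± 1.13 and 10.3 ± 0.189 (0.46, SE 0.13), the decapping enzyme Dcp2 0.40 (SE 0.13) and the helicase Ddx6 0.43 (SE 0.15). None passed the gene threshold. These are long transcripts (median exon length 8351 bases), and the list call was lost with the length and GC trend removed (0.071, adjusted p = 0.137).

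G2/M and mitosis genes were higher in 30 of 38 (median 0.13, and 0.24 without mimic 3; camera adjusted p = 0.0215; adjusted p = 0.631 with an estimated correlation). They included the spindle protein Aspm (6.65 ± 0.582 and 10.2 ± 0.977 FPKM; log2 fold change 0.54, SE 0.13), the cytokinesis scaffold Anln (0.42, SE 0.14), the kinetochore protein Ndc80 (0.40, SE 0.13) and the proliferation marker Mki67 (0.34, SE 0.13). That call was lost without mimic 1 or mimic 2 (0.13, adjusted p = 0.101 and 0.12, adjusted p = 0.0902) and with the length and GC trend removed (0.057, adjusted p = 0.136). G1/S and DNA replication genes were lower in 25 of 37 (median −0.082, adjusted p = 0.0254; adjusted p = 0.783 with an estimated correlation). Cyclin E1 (Ccne1), which drives S phase entry, read 7.65 ± 0.614 and 4.73 ± 0.146 FPKM (−0.59, SE 0.12) and passed adjusted over the list alone (limma adjusted p = 0.0442) but not over all genes. Pold1 (−0.40, SE 0.16), Gins2 (−0.44, SE 0.20) and the ligase Lig1 (−0.41, SE 0.21) followed. The median of this list turned positive without negative control 1, negative control 2 or mimic 3 (0.017, 0.010 and 0.063; adjusted p = 0.198, adjusted p = 0.153 and adjusted p = 0.848), while camera pointed lower in all 3 cases. The call was also lost with a mean FPKM of at least 5 (adjusted p = 0.0520). The 5 genes tested from the list of replication-dependent histones did not pass (median 0.15, −0.013 to 0.22 with 1 library left out, camera adjusted p = 0.863). Among them were Hist1h1c (0.19, SE 0.22), Hist1h2ae (0.33, SE 0.44) and Hist1h4i (−0.23, SE 0.39), multigene copies whose values are uncertain. H1f0 (0.15, SE 0.18) was also in the list, although it is not a replication-dependent histone.

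Apoptosis and p53 genes did not pass as lists. Apoptosis regulators had a median of 0.039 (18 of 31 higher; −0.0042 to 0.074 with 1 library left out), while their mean was −0.027 and camera pointed lower (adjusted p = 0.364), and p53 targets one of −0.021 (−0.16 without negative control 3; 11 of 23 higher, adjusted p = 0.175). Bax, the pore former of mitochondrial apoptosis, read 72.5 ± 6.89 FPKM in controls and 51.7 ± 1.67 with the mimic (log2 fold change −0.48, SE 0.11), the necroptosis kinase Ripk3 −0.30 (SE 0.12) and the caspase inhibitor Xiap 0.39 (SE 0.15). These stood at −0.14, −0.12 and 0.044 once the length and GC trend was removed. Cdkn1a, the p21 cell cycle inhibitor, read −0.37 (SE 0.14) and the polymerase Polk 0.40 (SE 0.13).

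Of the markers of other cell types, most lay under the filter. No epithelial marker had a value in the table, and the highest mean FPKM was 0.196 for fibroblast and stromal (Tagln), 0.418 for endothelial (Egfl7), 0.132 for neutrophil and mast cell (S100a8) and 0.953 for T and NK cell markers (Il7r). The 1 B cell marker tested was Ighm, at 42.8 ± 16.7 FPKM in controls and 45.8 ± 12.2 with the mimic (log2 fold change 0.15, SE 0.34). Of M2-like macrophage genes only 4 were tested, Tgfb1 (−0.41, SE 0.21), Clec10a (−0.34, SE 0.23), Vegfa (−0.22, SE 0.18) and Msr1, too few for a list test. Without negative control 3 Tgfb1 (−0.63) and Clec10a (−0.59) passed limma (adjusted p = 0.0164 and 0.0247), while Vegfa stood at −0.044 and Ighm at −0.22. With the length and GC trend also removed neither Tgfb1 nor Clec10a passed (limma adjusted p = 0.0797 and 0.0754). For Tgfb1 negative control 3 read 14.4 FPKM, within the 13.3 to 16.8 of the mimics, against 25.3 and 21.5 in the other controls. Its Clec10a value was 2.42, within the 2.40 to 3.30 of the mimics, against 4.82 and 4.62.

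Fold changes followed the length and base composition of transcripts. Spearman's rho across genes, which are not independent replicates, was −0.549 with transcript GC and 0.383 with exon length. The trend with GC was also seen in groupings other than the real one. Its absolute rho was 0.678 with negative controls 1 and 2 and mimic 3 on one side, and 0.560 with mimic 1 instead. Other groupings gave 0.0207 to 0.498. The 0.678 and 0.560 groupings still set negative controls 1 and 2 against 2 of the mimics, which is part of the real contrast. They cannot tell whether the trend goes with the mimic. With genes in 5 equal groups by GC, the median log2 fold change was 0.23 in the group with the lowest GC and −0.16 in that with the highest. From the shortest to the longest of 5 groups by exon length it went from −0.12 to 0.19. The same measure without negative control 3 gave rho −0.663 for GC. With this trend removed, 69 of the 129 named genes had estimates over 1.5 times smaller with the same sign, 5 over 1.5 times larger and 4 the other sign. On those values 0 genes passed limma (977 at an unadjusted p under 0.05) and 381 passed without negative control 3 (99 higher, 282 lower). Of the 15 list calls, 6 held: ribosomal proteins, oxidative phosphorylation, heat shock, hypoxia and glycolysis, the unfolded protein response and G1/S, all lower. With an estimated correlation none of the 6 held. Under quantile normalisation 7 lists passed, 3 higher and 4 lower.

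**Figure D4:**
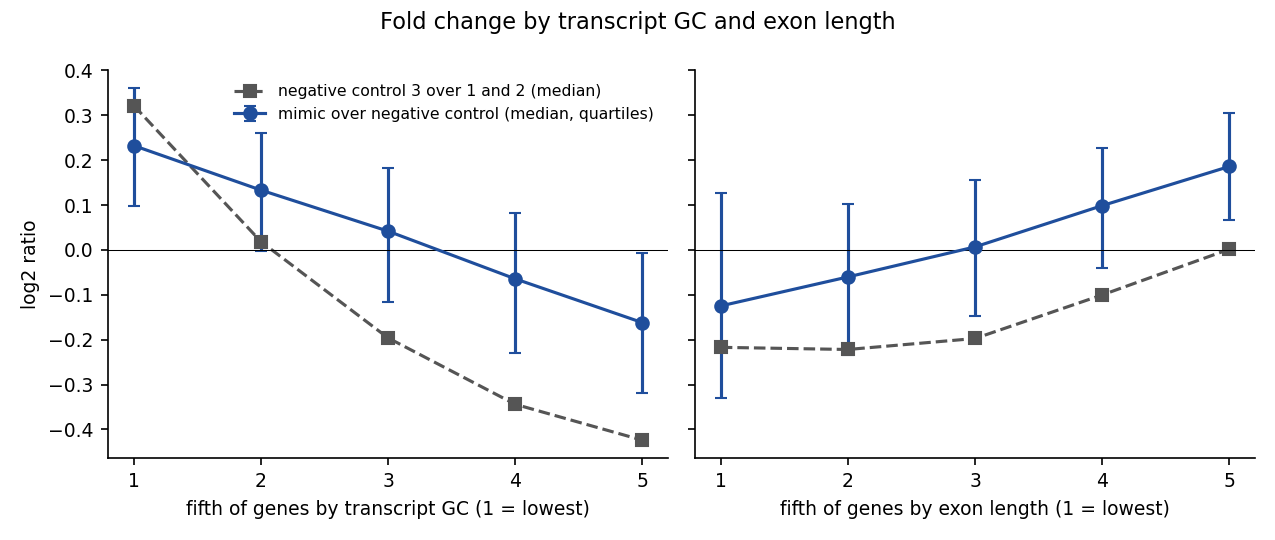
Median log2 ratio (vertical axis) of genes in 5 equal groups by transcript GC (left) and exon length (right); blue circles with quartile bars are mimic over negative control, grey squares negative control 3 over the mean of controls 1 and 2. The blue median went from 0.23 to −0.16 with rising GC and from −0.12 to 0.19 with rising length, and the grey one from 0.32 to −0.42 with rising GC.

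Negative control 3 stood apart from the rest. It had 13266 genes above 0, against 15141 to 15470 in the other 5 libraries. Its Pearson correlation with negative controls 1 and 2 was 0.944 and 0.946, while those 2 correlated at 0.994. It was nearer to every mimic than to its own group, at 0.962, 0.963 and 0.975 with mimics 1, 2 and 3. Mimic 3 correlated at 0.979 and 0.977 with mimics 1 and 2. The first principal component (53.2% of variance) ran from negative controls 1 and 2 to negative control 3, with the mimics between, and the second (25.6%) set mimics 1 and 2 against the controls. In that library 40.5% of genes expected at 3 to 20 fragments were at 0, against 6.43% to 10.6% in the others.

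**Figure D5:**
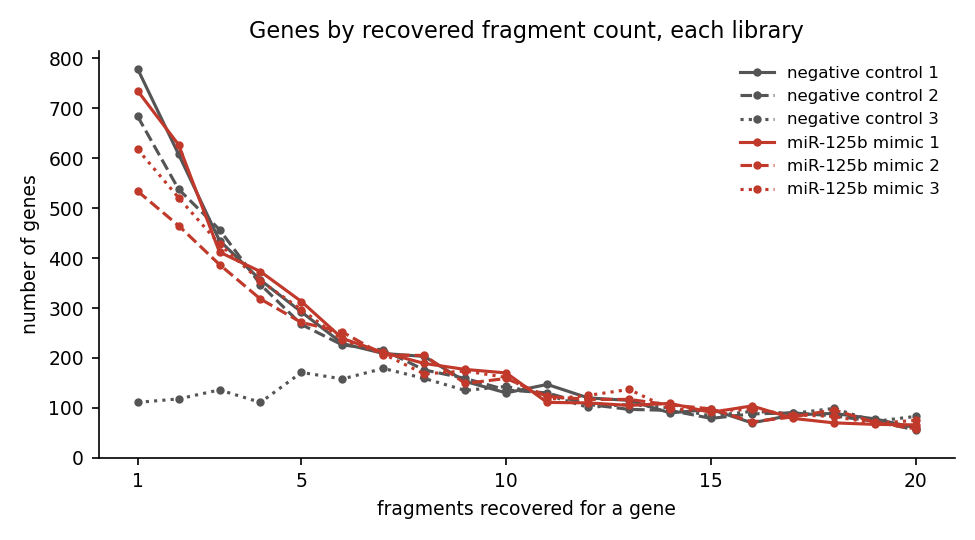
Number of genes (vertical axis) by recovered fragments per gene (horizontal axis), one line per library, grey for negative control and red for mimic, with line style giving the replicate. In 5 libraries 1 fragment was the most frequent value, with 534 to 779 genes; in negative control 3 it was 7, and 111 genes had 1.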

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

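The gene result depended on which libraries were kept and how they were weighed. No gene passed under other pseudocounts, filters, scalings, limma without a trend, voom, or the length and GC trend removed. With array weights 5276 genes passed (weight 0.086 for negative control 3). Leaving out 1 library each gave 0 to 2412, the latter without negative control 3, and leaving out replicate 3 of both groups gave 4377. With the trend also removed these were 381 and 2060. Of 129 named genes, 107 newly passed with array weights and 74 without negative control 3. The estimate of Txnip turned from 0.21 to −0.176 without replicate 3 of both groups and passed as lower there (adjusted p = 0.0316). The cause was not tested beyond the library left out.

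The number of lists past the threshold was 15, and 10 to 18 with 1 library left out. It was 7 under quantile normalisation, 0 with an estimated correlation (also 0 when negative control 3 or mimic 3 was left out), 6 with the trend removed and 6 with the trend removed and a replicate block. On the values as deposited, the block alone gave 0 genes and 13 lists, and changed no call beyond the 2 given in the report. The median of G1/S genes lay between −0.275 and 0.063 with 1 library left out. Immediate early genes stood at 0.038 without negative control 3 with the trend removed. The cause was not tested. The difference for genes with any seed site stayed positive, between 0.037 and 0.051 with 1 library left out, and passed an unadjusted 0.05 without negative control 1 (camera p of 0.0225) and without mimic 2 (camera p of 0.0499). It was smaller with the shortest 3′ UTR (0.020, camera p of 0.411) and with no filter (0.022, camera p of 0.132). The pyroptosis list passed in no setting. Depth limits what can be said of genes under 1 FPKM, which were not tested.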

Other observations

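The gene types and single genes in the next paragraphs were chosen only after the results were seen. Unclassified transcripts awaiting confirmation of their type (TEC in the annotation; 205 genes) had a median log2 fold change of 0.31 (camera adjusted p = 3.82e-10 over 6 gene types; the p with an estimated correlation was 0.187, unadjusted). Sense intronic transcripts (47 genes) stood at 0.17 (adjusted p = 0.00276; 0.248 with an estimated correlation), antisense transcripts (221) at 0.13 (adjusted p = 0.118) and lincRNAs (182) at 0.10 (adjusted p = 0.162). Protein-coding genes (9357) had a median of 0.032 and were lower than the rest (adjusted p = 0.00108; 0.219 with an estimated correlation). With the length and GC trend removed the TEC median was 0.14, and antisense transcripts (0.16, camera p of 2.82e-05; 0.242 with an estimated correlation) and lincRNAs (0.084, camera p of 0.00748; 0.0283 with an estimated correlation) were higher than the rest. Protein-coding genes were then lower (−0.0058, camera p of 4.42e-06; 0.000697 with an estimated correlation). These p are unadjusted. Without negative control 3, as deposited, the medians were 0.48 for TEC, 0.41 for sense intronic, 0.19 for antisense transcripts and 0.11 for lincRNAs. That of protein-coding genes was then −0.025. The strand setting is not known, so values of transcripts that overlap other genes are uncertain.

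Without negative control 3 and with the length and GC trend removed, 381 genes passed, a choice made after the data were seen. Lowest among named ones were the splicing factor Lsm5 (log2 fold change −1.35, SE 0.24), the coactivator Edf1 (−1.34, SE 0.078), Serf2 (−1.25, SE 0.096) and the ribosomal proteins Rpl15 (−1.23, SE 0.073) and Rpl28 (−1.23, SE 0.067). For Lsm5 the controls were unlike, at 9.80, 19.2 and 10.0 FPKM in negative controls 1, 2 and 3, against 6.99 to 8.82 in the mimics. In 324 of the 381 (85.0%), and 21 of the 24 listed with the largest folds, negative control 3 lay nearer to the mimics than to the other controls, so these calls rest on leaving it out. In Edf1 it read 8.83 FPKM against 34.0 and 36.4 in the other controls and 9.23 to 10.6 in the mimics. Highest were Insl3 (1.55, SE 0.22), the globin Hbb-bs (1.35, SE 0.24) and Ndufb1-ps (1.26, SE 0.20; 24.6 FPKM in negative control 3, above all 3 mimics), and Gapdhs was among them (1.18, SE 0.14). Several of these belong to families with pseudogenes and are uncertain.

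The tests on negative control 3 were chosen after its difference was seen. Its low number of genes above 0 is consistent with fewer distinct molecules behind its fragments: 8.44 fragments per molecule, against 2.19 to 2.90 in the other libraries. Fewer molecules cannot be the whole cause, because among genes with 5000 to 20000 fragments the SD of its log2 difference from negative control 1 was 0.573, against 0.113 between controls 1 and 2, where fewer molecules alone would give 0.054. The length and GC trend alone cannot be either, as the SD was 0.477 with the trend removed, against 0.181 between controls 1 and 2. Each test left the other cause in place, so both causes together were not tested. On a swap with mimic 3, mimic 3 correlated better with mimics 1 and 2 than with controls 1 and 2, by 0.0162 at the least. These correlations carry the length and GC trend, and negative control 3 and mimic 3 shared deviations (correlation 0.339). So small a margin therefore cannot exclude a swap. No biological explanation was tested.

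The tests on the lists were also chosen after their results were seen. The 6 libraries give 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 15 lists, the most of any (1 split as large), and the highest other split 13; for genes the real split gave 0 and the highest other 1, so all 10 were as large; for seed sites the real split gave 0.0495 (1 split as large) and the highest other 0.0267. Other splits that part all 3 pairs of same-numbered libraries gave 13, 0 and 2 lists. For the 9 lists past the threshold only before the length and GC trend was removed, the median absolute shift went from 0.144 to 0.102, which is 70.8% of it, so whether the trend made those calls cannot be told.

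With the trend removed, the split of negative controls 1 and 2 with mimic 3 against the rest gave 11 lists, more than the 6 of the real split. That split still set negative controls 1 and 2 against mimics 1 and 2, so an effect of the mimic would carry into it. If negative control 3 and mimic 3 were swapped, which is not excluded, it would be the true grouping. The 11 lists therefore cannot tell an effect of the mimic from differences between libraries that do not follow the groups. Either may account for list calls here, and their shares in the 6 were not separated.

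On seed sites, the test for a hidden fall through the trend was chosen after the result was seen, and that for mislabelled libraries before. With the length and GC trend removed no fall appeared, the 8mer difference being 0.0130 (interval −0.0055 to 0.035 over genes). That interval does not cover the spread between libraries. A fall of 0.1 added to the 8mer genes was detected with the trend removed (camera p of 6.57e-06, or 0.00115 with an estimated correlation). Smaller falls were not tried, so one of 0.05 cannot be excluded. For mislabelled libraries, the largest absolute 8mer difference over the 15 pairs of libraries was 0.0277. This too is an estimate without a spread between libraries. Genes with passenger strand sites were not lower either (0.010 for TAACCCG and 0.026 for TGACTTG with the trend removed). The level of miR-125b was not analysed here.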
